A study of Mus musculus with 6 samples.

How the data were processed

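RNA was sequenced from ciCPCs at passage 3 and passage 20, with 3 samples each. Per the labels, total RNA was purified on columns with DNase digestion and 10 µg entered a standard Illumina library protocol. The submitters' processing notes name HISAT2 2.0.5, SAMtools, HTSeq and DESeq2 with the mouse build GRCm38. Their roles, the annotation release and the strand setting are not given in the sources used here. The authors deposited whole-number counts per gene for each sample, and deposited values on a log2 scale that look like DESeq2 output, in which genes with 0 counts lie above 0. Which transformation produced the log2 values is not stated. The count files held 53801 genes, of which 29101 had a count. The log2 files held 32548 genes, including 4765 at 0 counts in all 6 libraries, and lacked 1318 counted genes with at most 8 counts in all. Tables of the whole series held the values of the per-sample files and were not used.

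Gene names, positions and types came from GENCODE M21 on GRCm38, which matched 53706 gene identifiers. The 95 others took 0.00623% of counts and were kept under their identifiers. Total counts in genes ranged from 11387738 to 17721788 per sample. Low-count genes were removed with filterByExpr, which left 15143 genes. Counts were scaled with TMM factors (1.12 to 1.13 at passage 3 and 0.873 to 0.917 at passage 20) and tested with edgeR 4.0.16 (robust quasi-likelihood test) in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The common biological coefficient of variation was 7.05%. Levels are TMM-normalised CPM, and a prior count of 2 entered log2 CPM values used for principal components. In the main setting the list tests were also run on those log2 CPM values. List medians, means and counts of calls came from edgeR's fold changes and tests instead.

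Samples were grouped by the passage in their labels, and passage 20 was compared with passage 3. The test, the alternatives, the rule for named genes and 30 gene lists were fixed before the data were examined. The rule named the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM in the higher group, groups that did not overlap and an established symbol. It also named the 5 most abundant called genes changed at least 2-fold, 11 regulators and cell cycle genes whatever their result, 5 sex-linked genes, and up to 2 members per direction of each list with the smallest adjusted p. Of the genes so named, 5 are not reported here. Other members named in the text were chosen after their values were seen. The lists covered cardiac progenitor regulators, early mesoderm, cardiomyocytes, smooth muscle, endothelium, fibroblasts and matrix, epicardium, neural, endoderm and epithelial, immune, skeletal muscle, cartilage and bone, and adipocyte genes. They also covered pluripotency, germline genes, S phase, mitosis, senescence, p53, Wnt, BMP and Activin, and FGF and ERK targets, glycolysis, the respiratory chain, mitochondrial DNA, sterol synthesis, ATF4 targets, interferon response, Hox and imprinted genes. Lists were tested against other genes with camera in limma 3.58.1 at a preset correlation of 0.01, and chromosomes likewise. After the data had been seen, 5 further lists were added, for HIF targets, limb patterning, MHC class I, tRNA synthetases and ribosomal proteins.

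Groups with 1 to 3 counts in all are given as a ratio of pooled counts with a 95% counting interval. A group at 0 counts is compared with a floor of 3 counts over the group. Gene overlaps were read from the annotation, and overlapping or antisense genes are uncertain. Those of the text not marked there, many with few counts in the partner, are Dgkg, Tril, Eef2, Pdgfra, Mki67, Ddx3y, Ryr2, Ptgis, Des, Mylk, Synpo2, Prrx1, Krt8, Otx2, Pax6, Sox17, Hapln1, Lipe, Tdh, Cdca8, Ei24, Nkd2, Id4, Spry1, Atp5c1, Uqcrc2, Cox5a, Slc2a1, Hk2, Axin2, Brdt, B2m, Tap1, Cars, Wars, Alx4, Pitx1, Hottip and Bhlhe40.

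The alternatives were RLE factors, upper-quartile factors, library sizes only, DESeq2 1.42.0, limma-voom, no low-count filter, at least 1 CPM in 3 libraries, and each library left out in turn. Others were a block for the replicate number, offsets for GC content and gene length fitted with mgcv 1.9.3, both together, a threshold of 0.01, camera with an estimated correlation, and fry. Thinning all libraries to the smallest total and limma on the authors' deposited log2 values were chosen after seeing the data. The log2 fold changes of those deposited values had a Pearson correlation of 0.943 with the edgeR values across 15143 genes, which are not independent, and the same sign in 99.6%, although 38 of 136 named genes differed by over 1.5-fold in the size of their change.

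The test was checked on simulated data drawn from the means and library sizes of the real samples, with 200 changed genes among 14848. It recovered 52 of 66 genes changed 1.5-fold (78.8%), 57 of 66 changed 2-fold (86.4%) and 64 of 64 changed 4-fold. Of 177 calls, 4 were false (2.26%), and camera called 0 of 100 unchanged lists. This speaks only for the comparison of passage 20 with passage 3 at these depths and with few changed genes. Rises and falls were simulated in balance, so the TMM scaling was not tested where most genes differ. Genes were drawn independently, so camera was not tested on lists whose genes move together. All libraries were given the same spread, so an outlying library such as passage 20 replicate 3 was not simulated.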

Results

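RNA sequencing counts were available for mouse chemically induced cardiovascular progenitor cells (ciCPCs), which are made from fibroblasts by reprogramming and were expanded after colonies had been picked on day 14. The cells grew in medium with BMP4, Activin A, the glycogen synthase kinase inhibitor CHIR99021, which activates Wnt signalling, and the FGF receptor inhibitor SU5402. The cells were wild type, on a mixed C57BL/6 and 129J/SvE background. The design held 3 libraries at passage 3 and 3 at passage 20, so the question was how the transcriptome of these progenitors differed between an early and a late passage. Libraries at passage 3 held 13995799, 14562684 and 17721788 counts in genes, and those at passage 20 held 11588496, 11387738 and 13285419. Levels are TMM-normalised CPM (counts scaled by each library's total multiplied by its TMM factor) as mean ± SD with n = 3 per passage. The labels do not say that the replicates were separate cultures, so all p-values measure only the spread between these samples, which may be technical. They also name no batch and do not say whether both passages came from the same colonies. An effect of passage therefore cannot be told apart from a difference between cultures, harvests or library batches. No molecular identifiers are named in the labels, so counting intervals and floors cover counting error only.

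The passages differed across most of the transcriptome. Of 15143 genes tested, 5604 were higher and 5641 lower at passage 20, together 11245 or 74.3% (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p under 0.05). At least 2-fold changes were called for 2022 genes higher and 2165 lower. The groups did not overlap in 11739 genes (77.5%), where chance gives 10%. Scaled by library sizes only, without TMM factors, the median log2 fold change of all genes moved from -0.01 to -0.34 and the share of calls that were higher fell from 49.8% to 29.9%, so directions of small changes are relative to the TMM scaling.

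The gene with the largest rise was Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), inducible nitric oxide synthase, which went from 0.545 ± 0.226 to 275 ± 20.4 CPM, 485-fold higher. Ascl2, a basic helix-loop-helix transcription factor, rose from 0.209 ± 0.0378 to 32.0 ± 4.71 CPM (144-fold). Kctd16 rose 122-fold, Dgkg, a diacylglycerol kinase gene, 94.9-fold, and the major histocompatibility gene H2-Q10 60.4-fold. A further 3 genes had 2 or 3 counts in all at passage 3, and pooled counts are given: H2-Q6 was 177-fold higher (counting interval 60.0 to 862), the chemokine gene Ccl5 108-fold higher (counting interval 36.6 to 530.3) and the carbonic anhydrase gene Car6 181-fold higher (counting interval 49.6 to 1505). Leaving out passage 3 replicate 2 moved the log2 fold change of H2-Q6 from 7.27 to 8.10 and of Car6 from 7.20 to 9.56, and leaving out replicate 3 gave 6.58 for Car6 and 7.26 for Ccl5 (from 6.56). All 8 passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (largest adjusted p = 1.95e-07). H2-Q6 and H2-Q10 have close paralogs that can share reads, so the split between them is uncertain.

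The largest falls included Tril (ENSMUSG00000043496, chromosome 6, 53815468 to 53820830), which encodes an interactor of Toll-like receptor 4, from 116 ± 1.20 to 0.567 ± 0.144 CPM, 205-fold lower. The ryanodine receptor gene Ryr3 fell from 92.4 ± 4.51 to 0.595 ± 0.265 CPM (155-fold) and Hoxd12 from 27.7 ± 0.670 to 0.215 ± 0.0278 CPM (123-fold). The remaining 5 had 2 or 3 counts in all at passage 20. Pooled, the transcription factor gene Sim1 was 245-fold lower (counting interval 83.8 to 1192), Hoxc12 256-fold lower (counting interval 70.6 to 2116), and the GABA receptor subunit genes Gabrb1 and Gabra4 193-fold lower (counting interval 65.8 to 938) and 138-fold lower (counting interval 46.9 to 669). Gpr165, an orphan receptor gene, was 145-fold lower (counting interval 49.3 to 703). Without passage 20 replicate 1 the log2 fold changes of Sim1 and Gpr165 were -8.73 and -10.64, and without replicate 3 those of Gabrb1, Gabra4 and Gpr165 were -8.28, -7.79 and -6.43. With all libraries they were -7.81, -7.46, -6.97 and -7.04 in the order Sim1, Gabrb1, Gabra4 and Gpr165. The 8 falls passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (largest adjusted p = 3.87e-08). Gabrb1 and Gabra4 overlap on opposite strands, as do Ryr3 and Aven, and the strand used in counting is not given in the sources used here, so their values are uncertain.

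Among genes changed at least 2-fold, the most abundant ones all rose. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), a collagen chain of interstitial matrix, went from 4353 ± 174 to 12539.6 ± 1260.0 CPM, 2.88-fold higher, and Col3a1 from 3675 ± 76.6 to 9378 ± 715 CPM (2.55-fold). The imprinted noncoding RNA H19 rose 2.31-fold, and the translation elongation factor genes Eef1a1 and Eef2 rose 2.12-fold and 2.29-fold. Eef1a1 has many pseudogenes, so its count is uncertain. The 5 genes had a largest adjusted p of 4.73e-08 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

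Regulators of cardiac progenitors moved both ways. Isl1 (ENSMUSG00000042258, chromosome 13, 116298281 to 116309689), a marker of second heart field progenitors, fell from 63.2 ± 5.72 to 7.45 ± 0.534 CPM, 8.44-fold lower, and Tbx1, another gene of that field, fell 25.1-fold (log2 -4.65, and -5.32 without passage 20 replicate 1). Nkx2-5 (ENSMUSG00000015579, chromosome 17, 26838664 to 26845009), a core cardiac transcription factor, rose from 1.15 ± 0.211 to 5.24 ± 0.371 CPM, 4.57-fold higher. Gata4 rose 1.70-fold, Mef2c 2.68-fold from 39.1 ± 2.63 to 105 ± 3.74 CPM, and Foxc2 5.25-fold, whereas Tbx5 fell 1.66-fold. Hand2 rose 1.18-fold from 151 ± 4.34 to 179 ± 5.29 CPM, but its log2 change turned to -0.090 with library sizes only, and it overlaps the antisense gene Hand2os1. The largest adjusted p of these 8 genes was 0.00122 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 23 list members tested, 12 rose, 9 fell and 2 did not pass, with 12 higher and 9 lower adjusted over the list alone. The list median was 0.24, the mean -0.05 and the test upward, and the median turned to -0.090 with library sizes only, where 11 rose and 9 fell. The list did not move against other genes (camera with Benjamini-Hochberg adjustment over 30 lists, adjusted p = 0.612).

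Early mesoderm genes were also mixed. T, the brachyury gene, rose from 1.40 ± 0.507 to 24.9 ± 1.24 CPM, 17.4-fold higher. Wnt3 rose from 1.68 ± 0.0261 to 11.1 ± 1.05 CPM (6.58-fold), and Mesp1, a gene of early cardiac mesoderm, rose 14.0-fold from 8 counts in all at passage 3 (log2 3.81, and 4.45 without passage 3 replicate 3). Evx1 fell 11.4-fold, from 27.5 ± 1.40 to 2.37 ± 0.634 CPM, and overlaps the antisense gene Evx1os. The receptor genes Pdgfra and Kdr, used to mark cardiovascular progenitors, fell 2.45-fold and 1.22-fold, Pdgfra from 328 ± 7.01 to 134 ± 0.744 CPM and Kdr from 90.8 ± 6.80 to 74.6 ± 4.15 CPM. These 6 genes had a largest adjusted p of 0.00382 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 15 members tested, 8 rose, 5 fell and 2 did not pass (8 higher and 5 lower adjusted over the list alone), with a median log2 of 0.51 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.704).

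**Figure D1:**
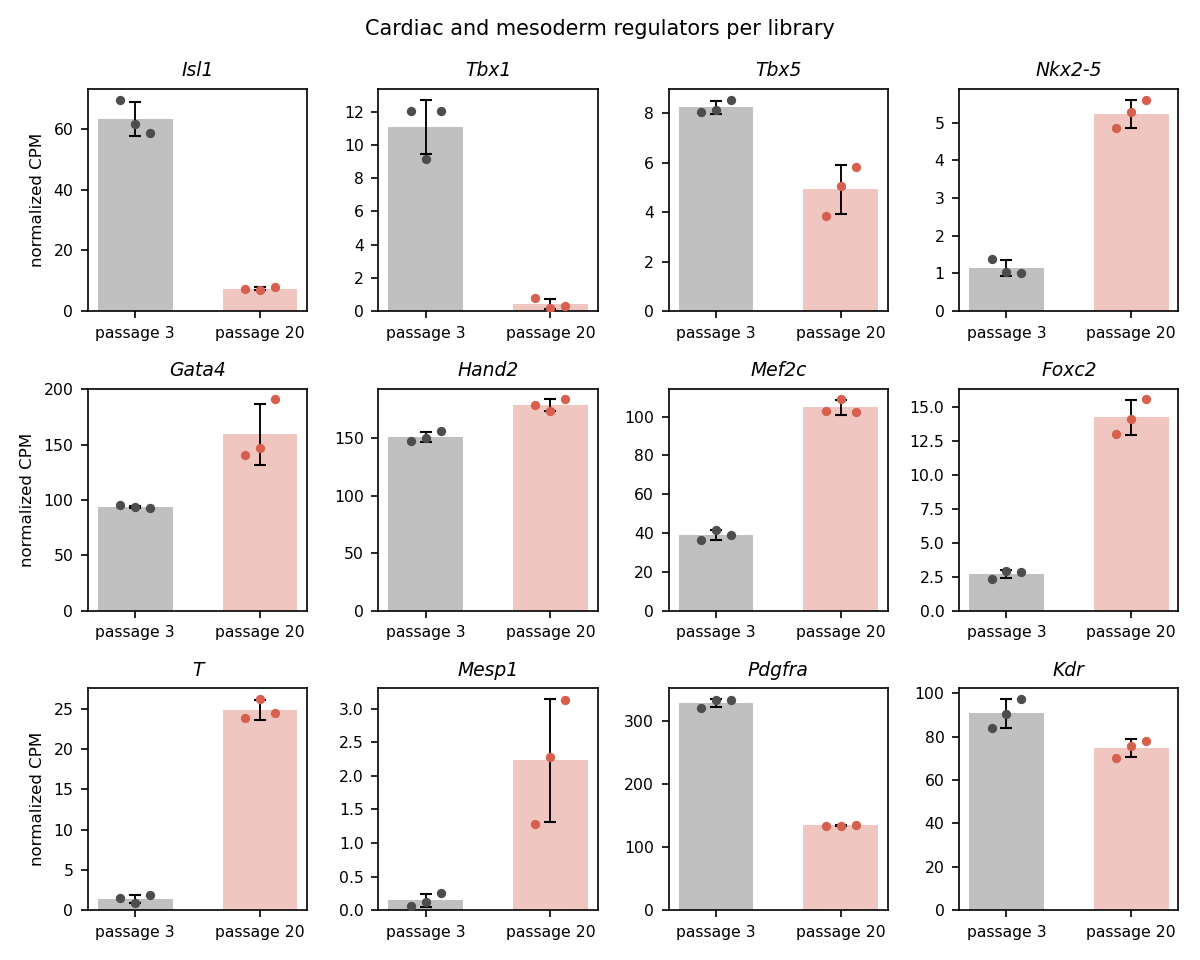
Each panel plots the normalised level of 1 regulator gene, in CPM from 0, at passage 3 and passage 20; points are the 3 libraries per passage, bars their mean and whiskers the SD. Isl1, Tbx1, Tbx5, Pdgfra and Kdr were lower at passage 20 and Nkx2-5, Gata4, Mef2c, Foxc2, T, Mesp1 and Hand2 higher, although the log2 change of Hand2 turned to -0.090 with library sizes only.

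Genes of differentiated cardiovascular cells moved both ways. Among sarcomere and ion handling genes of cardiomyocytes, Actc1 rose 2.30-fold and Tnnc1 2.25-fold, while the calcium release channel gene Ryr2 fell 1.86-fold and Lmod2 2.19-fold (log2 -1.13, and -1.72 without passage 20 replicate 3). Tnnc1 overlaps Nisch, which has far more counts on the opposite strand. Of 17 members tested, 9 rose, 3 fell and 5 did not pass (9 higher and 3 lower adjusted over the list alone), with a median of 0.50 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.104, and 0.0389 with library sizes only). In smooth muscle, Mylk, the myosin light chain kinase gene, fell from 56.6 ± 3.11 to 8.01 ± 0.991 CPM, 7.07-fold lower and Synpo2 2.51-fold, while Des rose 2.38-fold and Ptgis, prostacyclin synthase, 6.84-fold from 12.1 ± 0.116 to 82.7 ± 5.32 CPM. Here 3 of 16 rose, 11 fell and 2 did not pass (3 higher and 11 lower adjusted over the list alone), with a median of -0.59 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.104). In the endothelial list, Flt1 and Eng rose 4.14-fold and 3.17-fold, and Vwf and Erg fell 4.83-fold and 4.37-fold. Of its 10 members, 4 rose, 4 fell and 2 did not pass (4 higher and 4 lower adjusted over the list alone), with a median of -0.09 that turned to 0.22 with no low-count filter (camera with Benjamini-Hochberg adjustment, downward, adjusted p = 0.898, where the fry test pointed upward). Eng overlaps Fpgs on the opposite strand.

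Genes of glycolysis rose together. All 19 tested members were higher at passage 20 by edgeR's test (19 higher and 0 lower adjusted over the list alone), and by DESeq2, and the median fold was 3.88 (log2 1.96). Aldoc, an aldolase gene, rose from 18.0 ± 2.93 to 179 ± 13.6 CPM, 9.91-fold, and Pkm (ENSMUSG00000032294, chromosome 9, 59656368 to 59679375), pyruvate kinase, from 1108 ± 60.2 to 3306 ± 108 CPM, 2.98-fold (largest adjusted p = 4.6e-09, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Other members, named after their values were seen, included the glucose transporter gene Slc2a1 at 271 to 1921 CPM, hexokinase Hk2 at 80.5 to 781 CPM and lactate dehydrogenase Ldha at 949 to 2839.9 CPM. The list stood above other genes (camera with Benjamini-Hochberg adjustment, adjusted p = 8.09e-08), with an adjusted p = 0.50 with an estimated correlation. Part of Pkm overlaps Gm49759 on the same strand.

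Targets of ATF4 and genes of sterol synthesis rose as well. ATF4 is a transcription factor of stress responses such as that to missing amino acids, and amino acid supply was not tested. Of 16 ATF4 targets, 14 rose, 0 fell and 2 did not pass by edgeR's test (14 higher and 0 lower adjusted over the list alone). At an unadjusted p under 0.05 by that test, or by DESeq2, 0 fell. Psat1, an enzyme of serine synthesis, rose from 90.0 ± 4.86 to 429 ± 3.16 CPM, 4.77-fold, and Ddit3 from 11.4 ± 0.824 to 63.2 ± 2.85 CPM, 5.53-fold, the latter overlapping Mars on the opposite strand. Asns, asparagine synthetase, named after its value was seen, was at 58.2 to 376 CPM. The median was 1.95 (camera with Benjamini-Hochberg adjustment, adjusted p = 5.49e-06; adjusted p = 0.50 with an estimated correlation), and 1 member fell without passage 20 replicate 3 or with library sizes only. Of 20 genes of sterol synthesis and uptake, 19 rose and 1 fell (19 higher and 1 lower adjusted over the list alone). Dhcr7 rose from 60.8 ± 2.37 to 225 ± 2.91 CPM, 3.70-fold, while Mvk, mevalonate kinase, fell 1.36-fold (largest adjusted p of the 4 genes Psat1, Ddit3, Dhcr7 and Mvk = 0.000696, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The median was 1.42 (camera with Benjamini-Hochberg adjustment, adjusted p = 1.04e-06; adjusted p = 0.50 with an estimated correlation).

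Genes of mitochondrial respiration moved both ways. Of 28 nuclear-encoded genes of the respiratory chain and ATP synthase, 15 rose, 7 fell and 6 did not pass (16 higher and 7 lower adjusted over the list alone), and 9 rose without passage 3 replicate 2. Atp5c1 rose 1.55-fold and Uqcrc2 1.43-fold, and Cycs and Cox5a fell 1.57-fold and 1.32-fold. The median was 0.14 and turned to -0.19, with 5 higher and 17 lower, when library sizes only were used (camera with Benjamini-Hochberg adjustment, adjusted p = 0.204). Of 13 protein-coding genes of mitochondrial DNA, 0 rose, 7 fell and 6 did not pass by edgeR's test (0 higher and 7 lower adjusted over the list alone; 0 rose at an unadjusted p under 0.05 or by DESeq2), and 1 rose without passage 20 replicate 3. The complex I genes mt-Nd1 and mt-Nd5 fell from 1227 ± 81.6 to 358 ± 59.4 CPM, 3.43-fold and from 1389.9 ± 72.3 to 679 ± 76.0 CPM, 2.05-fold, while mt-Co1 stood at 2884 to 3137 CPM and did not pass. Reads of mt-Nd5 and mt-Nd6 cannot be told apart where they overlap. The list median was -0.28, and -0.57 with GC and length offsets (camera with Benjamini-Hochberg adjustment, adjusted p = 0.104, and 0.0353 with those offsets). Genes of mitochondrial DNA took 1.11 ± 0.0634% of counts at passage 3 and 0.630 ± 0.0356% at passage 20.

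Genes of fibroblasts and interstitial matrix were mostly higher. Of 24 tested, 19 rose and 5 fell (19 higher and 5 lower adjusted over the list alone), with a median fold of 1.87. Besides Col1a1 and Col3a1, Lum rose from 184 ± 5.44 to 440.2 ± 19.6 CPM, 2.39-fold and Col6a1 from 863 ± 45.5 to 2099.5 ± 92.2 CPM, 2.43-fold, whereas Prrx1, a mesenchymal transcription factor gene, fell 1.45-fold and Pdgfrb 1.60-fold (largest adjusted p = 1.07e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The list was higher than other genes (camera with Benjamini-Hochberg adjustment, adjusted p = 0.000894), with an adjusted p = 0.50 with an estimated correlation.

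Markers of other cell types went both ways. In the epicardial and mesothelial list, Krt19 rose from 5.37 ± 0.527 to 110.1 ± 9.68 CPM, 20.4-fold and Krt8 2.26-fold, while the uroplakin gene Upk1b fell 16.1-fold and Upk3b, with 3 counts in all at passage 20, was 40.6-fold lower (counting interval 13.7 to 198) (log2 -5.22, and -8.77 without passage 20 replicate 3). There 6 of 11 rose, 4 fell and 1 did not pass (6 higher and 4 lower adjusted over the list alone), with a median of 0.61, a mean of -0.09 and an upward test. Of 10 neural genes, 3 rose, 5 fell and 2 did not pass (3 higher and 5 lower adjusted over the list alone), and 3 fell without passage 3 replicate 2 or passage 20 replicate 1. Stmn2 fell from 61.7 ± 1.12 to 4.85 ± 0.807 CPM, 12.8-fold and Pax6 2.55-fold (log2 -1.35, and -2.25 without passage 20 replicate 3), while Tubb3 and Otx2 rose 2.74-fold and 1.58-fold. The neural median was -0.40. In the endoderm and epithelial list, 6 of 10 rose, 2 fell and 2 did not pass (6 higher and 2 lower adjusted over the list alone), with a median of 0.60. Cdh1, E-cadherin, rose 4.93-fold to 24.0 CPM and Epcam 4.04-fold, and Foxa1 and Sox17 fell 5.16-fold and 1.73-fold. Of 7 immune genes, 3 rose, 1 fell and 3 did not pass (3 higher and 1 lower adjusted over the list alone), with Cd74 3.19-fold and Cd14 3.27-fold higher and Mrc1 5.82-fold lower. The immune median was 0.26 and turned to -0.06 with library sizes only, where 2 rose and 1 fell. By camera with Benjamini-Hochberg adjustment none of these lists passed, with adjusted p of 0.560, 0.754, 0.184 and 0.560 in the order given.

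Skeletal muscle, cartilage and fat genes were similarly mixed. Of 11 skeletal muscle genes, 6 rose, 2 fell and 3 did not pass (6 higher and 2 lower adjusted over the list alone), with a median of 0.80. Acta1 rose 5.63-fold and the embryonic myosin gene Myh3 3.70-fold, while the perinatal myosin gene Myh8 fell 18.4-fold and Actn3 1.52-fold. Of 13 cartilage and bone genes, 6 rose and 7 fell (6 higher and 7 lower adjusted over the list alone). The cartilage genes Acan and Col9a1 rose 14.5-fold and 7.85-fold, Col9a1 from 5.15 ± 0.425 to 40.7 ± 3.45 CPM, while Hapln1 fell 6.50-fold and Sp7, a transcription factor gene of osteoblasts, 8.66-fold. The median was -0.73, the mean 0.11, camera pointed down and fry up. Of 5 adipocyte genes, 3 rose, 1 fell and 1 did not pass (3 higher and 1 lower adjusted over the list alone), though 2 and 3 fell without passage 3 replicate 1 and passage 20 replicate 3, where 7 were tested. Fabp4 rose from 0.826 ± 0.240 to 12.9 ± 2.46 CPM, 15.4-fold and Pnpla2 1.48-fold, and Lipe fell 1.67-fold. The adipocyte median was 0.15 and turned to -0.18 with library sizes only, where 1 rose, 2 fell and Pnpla2 lost its call (log2 0.23, from 0.56). By camera with Benjamini-Hochberg adjustment the 3 lists had adjusted p of 0.190, 0.878 and 0.602.

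Hox genes fell widely. Of 32 tested, 27 fell, 2 rose and 3 did not pass (2 higher and 27 lower adjusted over the list alone), with a median fold of 5.57 lower (log2 -2.48). Hoxa13 (ENSMUSG00000038203, chromosome 6, 52257694 to 52260880) fell from 39.2 ± 3.19 to 0.748 ± 0.0785 CPM, 52.1-fold, and Hoxd12 and Hoxc12 were among the largest falls of all genes. Hoxb9 rose 1.36-fold and lost its call without passage 3 replicate 1, passage 3 replicate 3 or passage 20 replicate 3 (log2 0.36, 0.43 and 0.32, from 0.45), and also with upper-quartile factors (0.37), library sizes only (0.12) or DESeq2 (0.45). The largest adjusted p of these genes was 0.0232 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Split by paralog group after the values were seen, all 11 tested members of groups 10 to 13 fell, with a median of -4.43 and a range from -7.80 to -3.09, against 16 of 21 in groups 1 to 9, with 2 higher and a median of -1.43. No test of this difference was run. The list stood below other genes (camera with Benjamini-Hochberg adjustment, adjusted p = 1.15e-06), with an adjusted p = 0.50 with an estimated correlation.

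**Figure D2:**
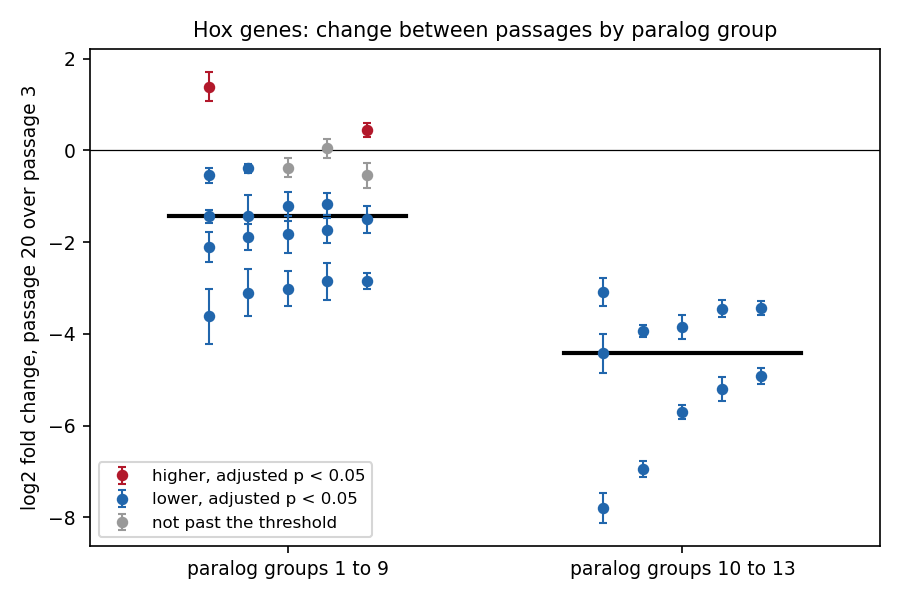
The log2 fold change from passage 3 to passage 20 (vertical axis) is plotted for each of the 32 tested Hox genes, with members of paralog groups 1 to 9 on the left and of groups 10 to 13 on the right; whiskers are 1 standard error, black bars medians and colours show the call. Members of groups 10 to 13 lie between -7.80 and -3.09 and all fell, while groups 1 to 9 have a median of -1.43 with 16 of 21 lower and 2 higher.

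Genes of mitosis rose slightly, and genes of DNA replication did not move together. Of 32 G2 and mitosis genes, 23 rose, 3 fell and 6 did not pass (24 higher and 3 lower adjusted over the list alone), and 5 fell without passage 20 replicate 3. Aurkb and Cdca8, of the chromosomal passenger complex, rose 1.68-fold and 1.63-fold, and Mad2l1 and Kif11 fell 1.72-fold and 1.24-fold. Mki67 stood at 400.4 ± 23.4 to 429.6 ± 55.2 CPM and did not pass (log2 0.10, -0.23 with library sizes only, and 0.17 and past the threshold without passage 20 replicate 3). The list median was 0.39 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.00422; adjusted p = 0.55 with an estimated correlation). With library sizes only 12 rose, 11 fell, that median was 0.06 and the list did not pass (0.0609). Of 32 replication genes, 11 rose, 13 fell and 8 did not pass (11 higher and 13 lower adjusted over the list alone), with Cdt1 and E2f1 2.09-fold and 1.59-fold higher and Ccne1 and Tyms 2.20-fold and 1.70-fold lower. Their median was 0.02, their mean -0.08 and the test downward (camera with Benjamini-Hochberg adjustment, adjusted p = 0.878). The median turned to -0.32 with library sizes only, where 2 rose and 21 fell, and to -0.06 with upper-quartile factors, and -0.03 without passage 3 replicate 3 or passage 20 replicate 2.

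Inhibitors of cyclin-dependent kinases, secreted factors linked to senescence and p53 targets were mostly higher. Of 17 genes in the senescence list, 12 rose, 3 fell and 2 did not pass (12 higher and 3 lower adjusted over the list alone), with a median of 0.63. The chemokine gene Cxcl1 rose from 10.0 ± 0.511 to 68.7 ± 2.72 CPM, 6.85-fold, while Igfbp3 fell from 555 ± 4.27 to 153 ± 4.86 CPM, 3.62-fold and Cdkn2c 1.53-fold. Cdkn1a, the p21 gene, named after its value was seen, was at 235 to 825 CPM. Cdkn2a, which encodes p16 and p19, rose 1.32-fold (log2 0.40), with no call at 0.07 with library sizes only or 0.19 with GC and length offsets. The list had a camera adjusted p = 0.0153 with Benjamini-Hochberg adjustment, an adjusted p = 0.50 with an estimated correlation and 0.0565 with GC and length offsets and a replicate block. Of 21 p53 targets, 15 rose, 1 fell and 5 did not pass (15 higher and 1 lower adjusted over the list alone), and 2 fell without passage 20 replicate 3. The apoptosis gene Bbc3 rose from 18.9 ± 0.949 to 101 ± 12.5 CPM, 5.37-fold and Eda2r 3.32-fold, and Ei24 fell 1.27-fold. The largest adjusted p of these genes was 0.00302 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The p53 list had a median of 0.56 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.000556; adjusted p = 0.50 with an estimated correlation).

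Among targets of the pathways set by the culture medium, those of Wnt signalling were mostly lower, and the lists of BMP and Activin and of FGF and ERK targets did not pass. Of 15 Wnt targets, 13 fell, 1 rose and 1 did not pass (1 higher and 13 lower adjusted over the list alone), with a median fold of 2.14 lower. Nkd2, a feedback inhibitor, fell from 190.0 ± 6.76 to 30.3 ± 4.84 CPM, 6.24-fold and Wif1, a secreted Wnt inhibitor, from 66.2 ± 1.99 to 19.7 ± 1.43 CPM, 3.36-fold, while Axin2 stood at 122 to 105 CPM and did not pass. Sp5 was the exception at 1.90-fold higher (log2 0.93, and 0.57 without passage 20 replicate 3). The Wnt list stood below other genes (camera with Benjamini-Hochberg adjustment, adjusted p = 0.000453; adjusted p = 0.50 with an estimated correlation). Of 20 BMP and Activin targets, 7 rose, 10 fell and 3 did not pass (7 higher and 10 lower adjusted over the list alone), with a median of -0.31. Smad7 and Skil rose 2.28-fold and 1.72-fold, and Id4 fell 16.6-fold from 17.6 ± 0.631 to 1.04 ± 0.226 CPM (camera with Benjamini-Hochberg adjustment, adjusted p = 0.754). Of 16 FGF and ERK targets, 10 rose, 2 fell and 4 did not pass (10 higher and 2 lower adjusted over the list alone), while 1 fell without passage 20 replicate 2 and 5 without passage 20 replicate 3. The immediate early gene Ier3 rose 8.55-fold and Spry1, a feedback inhibitor, 2.17-fold, while Il17rd fell 1.21-fold and Spred1 1.40-fold (log2 -0.48, -0.73 without passage 20 replicate 3, and no call at -0.40 without replicate 2 or -0.36 with GC and length offsets). That list did not pass (median 0.92, camera with Benjamini-Hochberg adjustment, adjusted p = 0.104), but reached 0.0394 without passage 20 replicate 1 and 0.0224 with library sizes only. The largest adjusted p of the named genes that changed was 0.0199 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

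Genes of pluripotency and of interferon responses were mostly higher. Of 14 pluripotency genes, 9 rose, 2 fell and 3 did not pass (10 higher and 2 lower adjusted over the list alone), with a median of 0.85. Pou5f1, the Oct4 gene, rose from 2.16 ± 0.539 to 13.2 ± 1.17 CPM, 6.06-fold and Lin28a from 3.12 ± 0.182 to 18.3 ± 4.07 CPM, 5.91-fold, while Dppa5a fell 4.65-fold and Tdh 2.10-fold. The call of Tdh was lost without passage 3 replicates 2 or 3 or passage 20 replicates 1 or 2 (log2 -0.92, -0.98, -0.77 and -1.16, from -1.07) and with DESeq2 (-1.09). Pseudogenes of Pou5f1 can share its reads. The list had a camera adjusted p = 0.0193 with Benjamini-Hochberg adjustment and an adjusted p = 0.51 with an estimated correlation. Of 17 interferon response genes, 10 rose, 1 fell and 6 did not pass (10 higher and 1 lower adjusted over the list alone), and 2 fell without passage 20 replicate 3. Cxcl10 and Bst2 rose 3.24-fold and 2.51-fold. Cxcl10 overlaps Art3 on the opposite strand. The median was 0.68 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0369; adjusted p = 0.55 with an estimated correlation), and the list did not pass without passage 20 replicate 3 (0.0732). The largest adjusted p of the named genes was 0.0297 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

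Germline and imprinted genes showed no common direction. Of 16 germline genes that DNA methylation silences, 2 were counted well enough to test, with Sycp1 1.55-fold higher and Brdt at 1.95 to 2.34 CPM not past the threshold. Thus 1 rose and 1 did not pass (1 higher and 0 lower adjusted over the list alone), with a median of 0.44 that turned to -1.37 with no low-count filter (camera with Benjamini-Hochberg adjustment, adjusted p = 0.602). The call of Sycp1 was lost without passage 3 replicates 1 or 3 or passage 20 replicates 1 or 2 (log2 0.61, 0.57, 0.44 and 0.58, from 0.63) and with library sizes only (0.30). Of 22 imprinted genes, 9 rose, 9 fell and 4 did not pass (9 higher and 9 lower adjusted over the list alone). Besides H19, Grb10 rose 3.49-fold from 9.45 ± 0.583 to 33.0 ± 2.48 CPM, and Peg12 and Nnat fell 3.57-fold and 1.65-fold, Nnat overlapping Blcap on the opposite strand. The imprinted median was 0.18 and turned to -0.16 with library sizes only, where 6 rose and 10 fell (camera with Benjamini-Hochberg adjustment, adjusted p = 0.825).

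**Figure D3:**
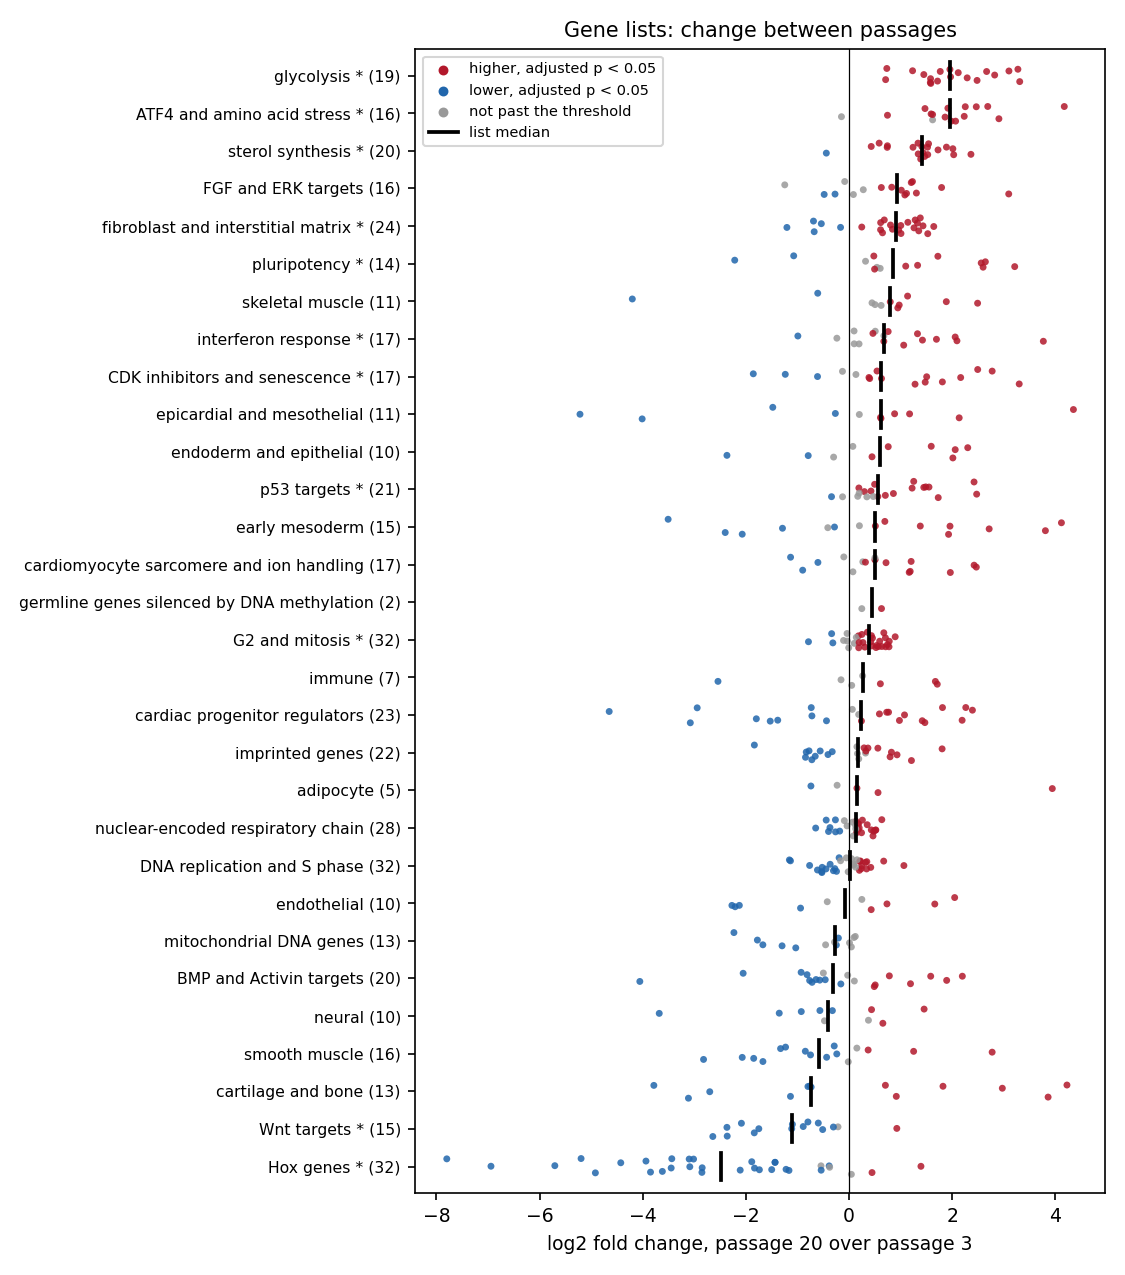
Each point is the log2 fold change from passage 3 to passage 20 of 1 gene (horizontal axis) in each of the 30 lists (vertical axis, number of tested members in brackets), red where called higher, blue where called lower and grey otherwise; black bars are list medians and asterisks mark camera adjusted p under 0.05. Medians run from -2.48 for Hox genes to 1.96 for glycolysis; with library sizes only, those of the cardiac progenitor, replication, adipocyte, immune, imprinted and respiratory chain lists turn negative.

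Of the 30 lists, 11 passed by camera with a preset correlation, 9 of them upward and 2 downward, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.50 after Benjamini-Hochberg adjustment. By fry, which asks whether a list's genes moved one way on balance, 22 passed.

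The libraries of a passage resembled each other. Spearman correlations across genes, which are not independent replicates, were 0.997 to 0.998 within passage 3, 0.991 to 0.997 within passage 20 and 0.916 to 0.937 between passages. The first principal component held 90.3% of the variance and separated the passages. The second held 4.64% and set passage 20 replicate 3 (-32.1) apart from replicates 1 and 2 (14.5 and 13.4). Replicate 3 also lay nearer passage 3 on the first component (55.7 against 75.7 and 72.7) and in Spearman correlation with the passage 3 libraries (0.932 to 0.937, against 0.916 to 0.920 for replicate 1 and 0.920 to 0.924 for replicate 2). No replicate pair was within sampling noise, with chi-square per degree of freedom of 1.68 to 2.46 at passage 3, 1.94 for passage 20 replicates 1 and 2, and 7.99 and 9.66 for the pairs with replicate 3. In that library the heat shock genes Hspa1a and Hspa1b stood at 5.76 and 17.4 CPM, against 60.5 and 62.3 and 198 and 195 CPM in the other passage 20 libraries and 1.43 ± 0.253 and 7.58 ± 0.766 CPM at passage 3. The immediate early genes Egr1 and Fos stood at 155 and 38.0 CPM against 39.1 and 31.3 and 17.8 and 17.9 CPM in the other passage 20 libraries and 80.7 ± 6.94 and 10.8 ± 0.129 CPM at passage 3. These genes were chosen after their values were seen, and Hspa1a and Hspa1b are near-identical paralogs. Without passage 20 replicate 3, 12369 genes were called.

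The makeup of the libraries also differed between passages. Genes of cytosolic ribosomal proteins took 2.27 ± 0.00791% of counts at passage 3 and 3.43 ± 0.0780% at passage 20, and the 10 most abundant genes 3.42 ± 0.0488% and 5.66 ± 0.286%. Pseudogenes can share reads of ribosomal protein genes, so the shares of those genes are uncertain. A count was found for 23575 ± 334 genes at passage 3 and 21801 ± 36.3 at passage 20, where libraries were also smaller. Sex-linked genes gave the same picture in all 6 libraries. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were present in each, and Xist had 12 counts in all at passage 3 and 5 at passage 20. Ddx3y rose 1.29-fold from 98.4 ± 3.73 to 127 ± 15.6 CPM, Uty 1.54-fold and Eif2s3y 1.36-fold (largest adjusted p = 0.0129, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and these calls were lost with library sizes only (log2 0.04, 0.29 and 0.10). Kdm5d stood at 58.0 ± 2.24 to 60.6 ± 6.54 CPM without a call and had a log2 change of 0.06, or -0.27 with library sizes only. Tested against all other genes, 0 of 20 chromosomes passed by camera with Benjamini-Hochberg adjustment (smallest adjusted p = 0.967), 0 had an unadjusted p under 0.05 and 0 passed with an estimated correlation. Small deviations from the other genes nonetheless separated the 3 libraries of each passage on 13 of 20 chromosomes. This count was made after the data were seen. Chance gives 10% only if the passages do not differ at all, and 77.5% of single genes also separated them. The count is therefore no sign of changed chromosome dosage. Random gene sets of equal size were not compared, so small shifts are not ruled out. The 13 chromosomes included chromosome X, with a median log2 change 0.13 above that of other genes, and chromosome 16, 0.08 below.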

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

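Thinning and the fit to the deposited log2 values were chosen after the results were seen; the other alternatives were planned. No gene list changed its side of the threshold with RLE or upper-quartile factors, DESeq2, limma-voom, the deposited log2 values or a replicate block. With library sizes only, 3528 genes were higher, 1328 at least 2-fold higher and 3371 at least 2-fold lower, and 163 genes were called in opposite directions. This follows from the shift of the median between the scalings. There the adjusted p of cardiomyocyte genes was 0.0389 and of FGF and ERK targets 0.0224, both past the threshold, and that of G2 and mitosis genes was 0.0609. The log2 changes of Hand2, Mki67 and Kdm5d turned to -0.090, -0.23 and -0.27. With no low-count filter the cardiomyocyte list (0.0467), FGF and ERK targets (0.0235) and mitochondrial DNA genes (0.0316) passed. The mitochondrial list also passed with GC and length offsets (0.0353) and with those and the replicate block (0.0276), where CDK inhibitors and senescence did not (0.0565). Interferon response did not pass with at least 1 CPM in 3 libraries (0.0643) or after thinning (0.0544). At a threshold of 0.01, pluripotency (0.0193), CDK inhibitors and senescence (0.0153) and interferon response (0.0369) did not pass. The deposited log2 values gave 1419 genes at least 2-fold lower and smaller changes in genes with few counts in a group: the Hox median was -1.22 (from -2.48), and log2 changes were 3.53 for H2-Q6 (from 7.27), 3.17 for Car6 (from 7.20), -4.49 for Sim1 (from -7.81) and 1.43 for Nkx2-5 (from 2.19). Leaving out each library in turn gave adjusted p from 0.0394 to 0.315 for FGF and ERK targets and from 0.00814 to 0.0732 for interferon response. The causes were not tested.

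With an estimated correlation the 11 lists that had passed did not. Adjusted p was 0.50 for fibroblast and matrix, CDK inhibitors, p53, Wnt, glycolysis, sterol, ATF4 and Hox lists, 0.51 for pluripotency, and 0.55 for G2 and mitosis and for interferon response. By fry 11 more lists passed: cardiomyocyte (0.00167), smooth muscle (0.00180), epicardial (0.000240), endoderm and epithelial (0.000103), immune (0.000331), skeletal muscle (0.00397), adipocyte (0.00186), germline (0.0478), FGF and ERK targets (0.00837), respiratory chain (0.00480) and mitochondrial DNA (0.00762). Fry does not compare a list with other genes.

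The values gave no sign that the replicate numbers pair the libraries, and the labels do not say whether they do. Deviations of same-numbered libraries correlated at -0.03 to 0.05, none over 0.1, and 2 of 6 libraries correlated best with their own number. With the replicate block 11103 genes were called against 11245. Across the left-out libraries calls ranged from 10533 to 12369. Depth limits the low-count genes, where libraries at passage 20 were smaller.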

Other observations

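The tests of HIF targets, of residual fibroblasts and of admixed embryonic stem cells, and the 5 gene lists described first, were chosen after the result was seen. Genes of antigen presentation by MHC class I rose. Of 13 tested, 12 rose, 0 fell and 1 did not pass by edgeR's test (0 fell at an unadjusted p under 0.05 or by DESeq2, and 1 fell with library sizes only). H2-K1 rose from 24.3 ± 1.88 to 257 ± 31.4 CPM, 10.5-fold, H2-D1 5.60-fold, beta-2 microglobulin B2m from 126 ± 6.66 to 311 ± 35.7 CPM, 2.48-fold and the peptide transporter gene Tap1 3.38-fold. Paralogs among the H2 genes can share reads. The list median was 2.49. Genes of protein synthesis rose as well. Of 79 cytosolic ribosomal protein genes, 77 rose and 1 fell, with a median log2 change of 0.86. This list was drawn by gene symbol, so it takes in paralogs such as Rpl7l1, the 1 that fell (log2 -0.70). Pseudogenes can share reads of ribosomal protein genes, so their single counts are uncertain. Of 20 cytosolic tRNA synthetase genes, 17 rose and 1 fell. Among these Cars rose from 59.9 ± 4.09 to 292 ± 16.8 CPM, 4.87-fold and Nars from 145 ± 3.73 to 463 ± 28.0 CPM, 3.19-fold, while Wars fell 1.16-fold, a call that depends on which libraries are kept. Without passage 3 replicates 1 or 3 or passage 20 replicates 1 or 2, 0 synthetase genes fell, and without passage 20 replicate 3, 2 fell, as did 3 with library sizes only.

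Genes that pattern the limb fell along with the posterior Hox genes. Of 13 tested, 10 fell, 2 rose and 1 did not pass. Tbx4, a gene of hindlimb identity, fell from 169 ± 2.98 to 11.7 ± 1.03 CPM, 14.4-fold, Alx4 from 117 ± 2.73 to 4.16 ± 0.839 CPM, 27.8-fold and Pitx1 2.00-fold. Of the noncoding RNAs of the Hox clusters, Hotair had 168 counts in all at passage 3 and 0 at passage 20, at least 34.9-fold lower against a floor of 3 counts over the group, and Hottip was 37.6-fold lower (counting interval 12.7 to 184) with 3 counts at passage 20. Meis2 and Grem1 rose 1.98-fold and 1.52-fold. By camera with Benjamini-Hochberg adjustment over 35 lists, adjusted p was 2.14e-05 for MHC class I, 7.97e-17 for ribosomal proteins, 9.25e-06 for tRNA synthetases and 0.0142 for limb patterning, and adjusted p = 0.39 for each with an estimated correlation. These lists were picked because their genes had been seen to move, so their counts and tests are no independent evidence.

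Higher glycolysis genes at passage 20 were weighed against GC content, depth and a hypoxia-type response. With GC and length offsets the list median stayed at 1.96, so that trend does not account for the pattern. With every library thinned to the smallest total 19 genes were still called higher, so the calls do not need unequal depth. Levels were already scaled for depth and the changes were large, so thinning could hardly have removed these calls and is a weak test. The 16 HIF targets outside glycolysis all rose, with a median of 2.34 (camera with Benjamini-Hochberg adjustment, adjusted p = 1.43e-07; adjusted p = 0.39 with an estimated correlation), among them Bhlhe40 (14.0-fold), Egln3 (13.2-fold) and Vegfa (from 146 ± 13.8 to 1371 ± 142 CPM, 9.36-fold), which is consistent with a hypoxia-type response in the late cultures. These 16 had been looked at before the prediction was written, and 4 further targets seen to be higher first were left out, which lowered the median. The pattern had also first included ATF4 targets and sterol genes, for which no such test was run. Cell density, oxygen and time since the last medium change were not given, so a difference in culture state at harvest remains open beside an effect of passage.

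Lower Hox genes were weighed against GC content and loss of residual fibroblasts alone. With GC and length offsets the median was -2.45. If fibroblasts left over from reprogramming had only been lost, their markers would have fallen too, but the fibroblast list had a median of 0.90 with 19 of 24 genes higher. Progenitors may express matrix genes themselves, so a loss of fibroblasts together with a rise of matrix genes in the progenitors stays open. Whether the passages came from colonies with different positional identity is untested, and a first test of that from same-numbered libraries was dropped after it was run because the labels name no colony.

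Higher pluripotency genes were weighed against GC content and admixed embryonic stem cells. With GC and length offsets the median was 0.84. Of members past the low-count filter 1 (Dppa5a, from 2.32 ± 0.414 to 0.490 ± 0.0900 CPM) was lower with all libraries and without each library in turn, which added cells alone would not bring about, but 1 gene is too few to decide on admixed embryonic stem cells. The count depends on the rule, which was revised after results were seen: 2 members (Dppa5a and Tdh) were lower with all libraries, and with no low-count filter 4 of 21 were lower, 2 of these (Dppa5a and Nr0b1) also without each library, Nr0b1 with 1 count in all at passage 20 (19.3-fold lower, counting interval 3.22 to 788). A stem cell reference was not used here and other members rose, so a change within the progenitors and an admixture cannot be told apart.

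The 6 libraries can be split in 10 ways, too few for a share under 0.05. The real split called 11245 genes and the highest other split 0 (1 of 10 splits as large), and 4187 against 0 for changes of at least 2-fold (1 of 10). Every other split mixed libraries of both passages, so the passage difference entered its spread and few calls were bound to follow. For gene lists the real split gave 11 and the highest other 13 (6 of 10 splits as large), and for chromosomes 0 and 0 (10 of 10). Mixed splits still held part of the passage difference, so their list counts do not show what unrelated libraries would give.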
